A study of Mus musculus with 5 samples.

How the data were processed

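Thymic NKT cells from wild-type (3 samples) and IL-15-deficient (2 samples) mice were each measured on 1 Agilent 1-colour array. Per the labels' protocols, each sample was a T-cell-enriched suspension of 10 pooled thymi from which CD3e-positive, CD1d-tetramer-positive cells were sorted. Groups and replicate numbers were taken from the labels. The labels do not say that the replicates of a group came from separate pools of animals, so the p-values measure only the spread between these samples, which may be technical.

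Per the file headers, the deposited scanner files hold linear spot intensities from Agilent Feature Extraction 10.7.1.1. Its processed signal is background-subtracted and detrended within each array, with no scaling between arrays. The submitters' processing notes also name limma, with no version and no settings. The authors' deposited value table holds intensities on a linear scale. Set against the scanner columns, it equals the spot median minus the local background median plus a constant per array for bright spots, and its column medians differ (25.2, 22.6 and 26.0 in wild-type 1 to 3, 24.4 and 15.8 in IL15ko 1 and 2), so it is not scaled between arrays. The software setting behind the constant stays unknown. All 5 arrays were on 1 slide, so slide and scan could not be tested as batches.

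The main values were log2 of the processed signal minus each array's 75th percentile. Since under 50% of the probes were well above background on every array, the percentile was taken over the 18527 probes well above background on all 5 arrays, as for other arrays with low detection. Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged. No probe was saturated. The scanner files used here carry no gene symbols. The accessions in them were matched, without versions, to NCBI's annotation of mouse assembly GRCm38.p6, which named 26425 of the 55681 probes with 1 symbol, 0 with several and left 29256 unnamed. Unnamed probes stayed out of the main comparison. The files name no genome build, so no coordinates are given. Each of the 20022 genes with a probe was represented by its brightest probe, and 11998 genes whose probe was well above background on at least 2 arrays were tested. Of the 879 called genes, 209 had several measured probes, and in 18 of these the probes differed in sign.

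Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The fit had 3 residual and 2.28 prior degrees of freedom. Errors of log2 differences are limma's moderated standard errors, and confidence intervals of folds are at 95%. A gene not well above background in 1 group has only a bound of its fold, the mean of the bright group against the mean, per array of the dim group, of the higher of the lowest signal among probes well above background and the probe's own signal. This applied to 58 called genes. The number of arrays limits the precision.

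A total of 28 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move one way and does not compare them with other genes. With an estimated correlation 0 lists were called (smallest adjusted p = 0.202). This loss is not due to correlation alone. At a preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it takes them from the 3 residual degrees of freedom. The p-values at the preset correlation thus do not carry the uncertainty of a spread estimated from 5 arrays. The NKT2 list had an estimated correlation of 0.00965, near the preset, yet its unadjusted camera p rose from 9.29e-08 to 0.0128. Fry called 13 lists, among them anti-apoptotic genes (fry adjusted p = 0.0231) but not ribosomal proteins (fry adjusted p = 0.121). The lists, the design, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took IL-15 and its receptor chains, the 8 largest changes per direction among called genes well above background on all 5 arrays with groups that do not overlap, up to 4 members of each list by smallest p and any member needed to describe a count, and up to 4 genes per direction with a bound. Accession-type names were left out. Some list members named below, such as Ifng, Klrb1c, Prf1, Il4 and Gata3, were not among the 4 with the smallest p of their list. Sterol, Y-linked and unnamed features were named after their values were seen.

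The fit was tested on simulated arrays built from the means and spreads of 11989 genes, with 200 genes changed, for the comparison of IL15ko with wild-type. It recovered 38.5% of genes changed 2-fold, 90.9% of those changed 4-fold and 99% of those changed 16-fold, and 5.28% of its calls were unchanged genes. Camera called 100% of simulated lists shifted 2-fold and 10% of lists that were not shifted, over 20 simulations. The simulated genes varied independently, with the spreads shuffled among genes and no array effects. Measured genes varied together in some lists (estimated correlation of 0.506 for cell-cycle genes), so these rates may not hold for the data.

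Alternatives were a normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim probes, a filter for all 5 arrays, outlier spots kept, the mean of a gene's measured probes, the authors' deposited table, a trended and robust prior, array weights, the replicate number as a block and leaving out each sample. The files used here hold no mean spot signal, so normexp ran on median spot and background signals. Alternatives added after seeing the data were the 75th percentile over all probes, normexp without an offset, wild-type 1 and 2 as 1 replicate, unnamed features tested with the named genes, and X and Y genes left out. Figures were drawn with matplotlib.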

Results

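Gene expression was measured by 1-colour microarray in natural killer T (NKT) cells from the mouse thymus. NKT cells are T cells that recognise lipids presented by CD1d, and here they were sorted as CD3e-positive cells that bound a CD1d tetramer. The 5 arrays comprised 3 from wild-type C57BL/6 mice and 2 from mice lacking interleukin-15 (IL15ko), a cytokine needed by NK cells and memory T cells. Each sample came from 10 pooled thymi. Of the 55681 probes, 44.6%, 46.8% and 49.6% were well above background on wild-type arrays 1, 2 and 3, and 45.2% and 33.9% on IL15ko arrays 1 and 2. IL15ko 2 was thus the dimmest array. Wild-type 1 and 2 were unusually close to each other, with a robust SD of their log2 difference of 0.107. The other pairs within a group lay at 0.243 for wild-type 1 and 3, 0.26 for wild-type 2 and 3, and 0.304 for the IL15ko pair. The value of 0.107 was 1.41 times that expected from repeated spots, but repeated spots measure spot noise only, so this does not show whether wild-type 1 and 2 were separate samples. They were counted as separate because the labels number them as replicates.

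The design asks which genes differ in thymic NKT cells between mice with and without IL-15. The probe for Il15, the targeted gene, was not well above background on any of the 5 arrays, so it checks nothing about the labels. The receptor chains showed no change past the threshold in the main setting. Il2rb, the signalling chain shared by the IL-2 and IL-15 receptors, had a log2 difference (IL15ko minus wild-type) of -1.56 ± 0.33 (SE) and a limma adjusted p of 0.054, and was called lower in 7 of 19 alternatives. Il15ra had a log2 difference of -0.45 ± 0.35 and an adjusted p of 0.439, and its other probe had a log2 difference of -1.155. Il2rg, the common gamma chain, had one of 0.46 ± 0.21 and an adjusted p of 0.233. Of the 12 measured genes of IL-15 signalling, 0 passed the test over all genes, and 1 was higher and 1 lower when adjusted over the list alone (Jak3 and Il2rb). Their mean log2 difference was -0.06 and their median 0.01, and camera gave an upward direction with an adjusted p of 0.84.

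NKT cells of IL15ko mice had far lower levels of killer-cell genes, and higher levels of genes of the NKT2 and NKT17 subsets. The 8 largest falls among genes measured on all 5 arrays were in Gzma (52.2-fold lower, 95% confidence interval 42.5 to 64.1) and Gzmb (44.8-fold, 23.3 to 86.1), which encode granzymes, in the NK receptor genes Klra5 (38.3-fold, 22.2 to 66.1), Klre1 (31.7-fold, 15.2 to 66.3) and Klrc3 (12.5-fold, 4.49 to 34.8), in Tsc22d3 (29.3-fold, 8.95 to 95.9), a glucocorticoid-induced gene, in the chemokine gene Ccl5 (25.8-fold, 14.7 to 45.3) and in Il10ra (11-fold, 7.92 to 15.4), a chain of the IL-10 receptor. Without IL15ko 1 the log2 differences of Gzmb, Klre1, Tsc22d3 and Klrc3 were -4.86, -4.27, -4.09 and -2.73, and without IL15ko 2 they were -6.11, -5.71, -5.65 and -4.55. The call of Tsc22d3 was lost without either (adjusted p = 0.0704 and 0.0647) and that of Klrc3 without IL15ko 1 (adjusted p = 0.0562). Confidence intervals of folds cover the spread between arrays only, not the choice of processing. Over 19 alternatives the smallest falls had log2 differences of -3.67 for Klra5, -3.57 for Klre1, -1.72 for Klrc3 and -2.37 for Il10ra. These lie outside the intervals above. For Gzma, Gzmb, Ccl5 and Tsc22d3 they were -4.9, -4.52, -4.21 and -3.64. The 8 largest rises were smaller. They were in Il1r1 (5.05-fold higher, 3.64 to 7.01), an IL-1 receptor, Begain (5.05-fold), the receptor phosphatase gene Ptprf (5.04-fold), Nrp1 (4.73-fold), which encodes neuropilin-1, Coro2b (4.53-fold), Clstn3 (4.21-fold), Pou2af1 (4.17-fold), a transcriptional coactivator gene, and Pcsk1 (4.16-fold).

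Some genes were well above background in one group only, so that only a lower bound of the fold can be given, taken against the lowest signal above background on each array or the probe's own signal where that was higher. Styk1 was at least 17.8-fold lower in IL15ko (adjusted p = 0.00591), Klri2 at least 16.3-fold (adjusted p = 0.021, with log2 differences of -4.09 in the main fit, -3.16 without IL15ko 1, which is below that bound, and -5.03 without IL15ko 2), Wdr95 at least 14.4-fold (adjusted p = 0.000846) and Klrk1, which encodes the activating receptor NKG2D, at least 12.8-fold (adjusted p = 0.00304). In the other direction, Xist was at least 23.8-fold higher in IL15ko (adjusted p = 0.00559), Emilin1 at least 4.78-fold (adjusted p = 0.0103), Kif15 at least 3.86-fold (adjusted p = 0.0312) and Clspn at least 3.77-fold (adjusted p = 0.0328). These bounds hold for the background correction of the main fit only. Of the 12 genes given here or below as a bound, all 12 had a smaller log2 difference than their bound with normexp and an offset of 50, where 0 were called (Styk1 -2.31, Wdr95 -1.96, Klrk1 -1.69, Xist 2.69), and 9 had one in the authors' deposited table.

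In total, limma called 450 genes higher and 429 lower in IL15ko among 11998 tested, at a Benjamini-Hochberg adjusted p under 0.05. Of these, 292 were at least 2-fold higher and 286 at least 2-fold lower. The values of both groups did not overlap in any of the 879 called genes, nor in 47.2% of all tested genes, where chance gives 20% for 3 arrays against 2. The counts rest on few arrays. In both directions together, 9 genes were called without wild-type 1, 104 without wild-type 2, 785 without wild-type 3, 336 without IL15ko 1, 192 without IL15ko 2, and 96 with wild-type 1 and 2 averaged into 1 sample. The counts were 0 higher and 1 lower with a normexp background correction and an offset of 50, 0 and 3 without the filter on dim probes, and 822 and 698 with a trended, robust variance prior. With 3 arrays against 2, the smallest two-sided p that an exact permutation test of a single gene can give is 0.1.

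**Figure D1:**
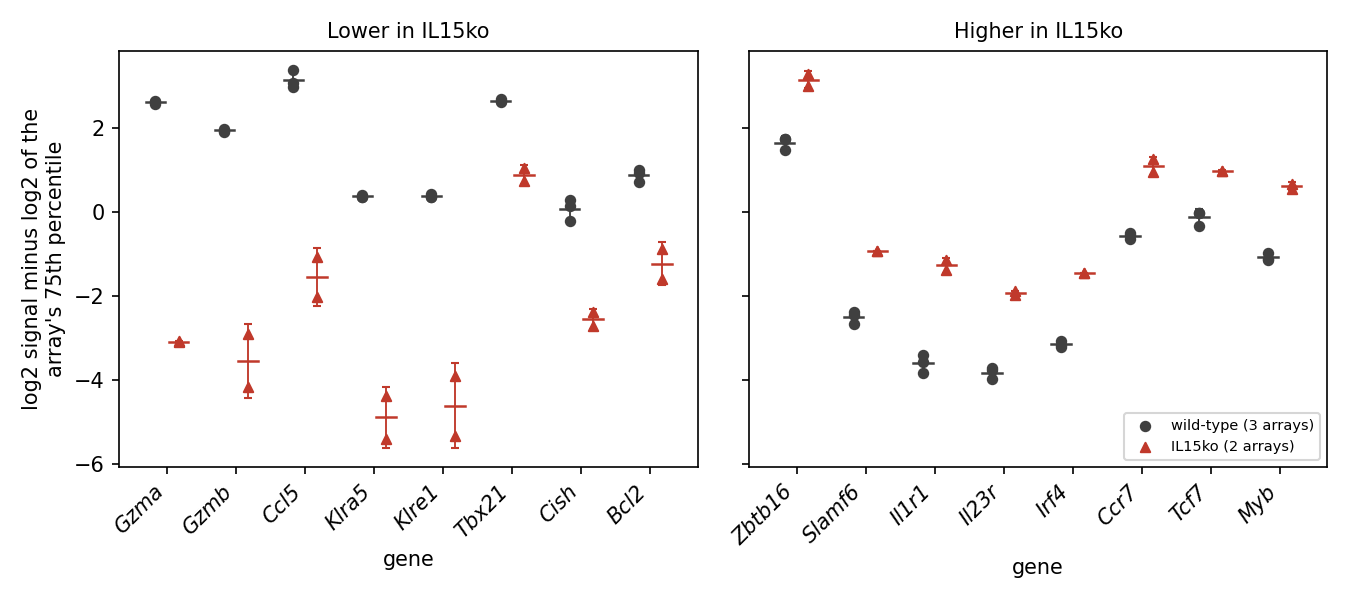
Log2 signal of 16 genes, relative to the 75th percentile of each array, in the 3 wild-type arrays (circles) and the 2 IL15ko arrays (triangles). Points are arrays, horizontal lines are group means and error bars are SDs. In the left panel Gzma had a mean of 2.61 in wild-type and -3.09 in IL15ko, and in the right panel Zbtb16 had a mean of 1.64 in wild-type and 3.15 in IL15ko.

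Genes of NK-cell receptors and their adaptors were lower as a group. Of 25 measured members, 22 were called lower, 0 higher and 3 did not pass. Adjusted over the list alone, 23 were lower. The mean log2 difference was -2.46 (camera adjusted p = 3.59e-21, and adjusted p = 0.202 with an estimated correlation). Klrk1 and Klri2 have been given above. Klrc1, an NKG2 receptor gene, was at least 9.47-fold lower, Klra6 7.10-fold and Klra8 5.61-fold. Klrb1c, which encodes NK1.1, fell by 1.75 on the log2 scale (3.36-fold, adjusted p = 0.0139), while Cd226, with a log2 difference of -1.36 ± 0.32, did not pass (adjusted p = 0.068). The Klra genes (Ly49 receptors) and the Klrc genes are near-identical copies of one another, so that a probe may bind more than one of them and the values of single members are uncertain. Of the list of NK and innate lymphoid cell genes, 5 were measured, 3 were called lower (Klra8, Klre1 and Klra4) and 2 did not pass (Irf8 among them), and adjusted over the list alone 4 were lower. Those 3 are also on the NK receptor list. The mean was -2.04 (camera adjusted p = 4.12e-05, and adjusted p = 0.219 with an estimated correlation). Ncr1, a receptor gene of NK cells, was not well above background on any array, and Eomes was so on 1 wild-type array.

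Cytotoxic effector genes fell in part. Of 19 measured members, 8 were called lower, 0 higher and 11 did not pass, and adjusted over the list alone 10 were lower. The mean log2 difference was -1.24 (camera adjusted p = 2.83e-06, and adjusted p = 0.219 with an estimated correlation). Besides the granzymes Gzma and Gzmb, Gzmc was 4.40-fold lower, Fasl, the ligand of the death receptor Fas, 4.79-fold, and Tnfsf10, which encodes TRAIL, 2.98-fold. Prf1, which encodes perforin, had a log2 difference of -1.29 ± 0.28 and an adjusted p of 0.0603. The markers of NK cells given above moved in the same direction.

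The list of T-bet and NKT1 genes, the interferon-gamma-producing NKT programme, shifted down. Of 24 measured members, 12 were called lower, 0 higher and 12 did not pass, and 18 were lower when adjusted over the list alone. The mean was -1.55 (camera adjusted p = 8.34e-11, and adjusted p = 0.219 with an estimated correlation). Tbx21, which encodes T-bet, fell by 1.77 ± 0.15 on the log2 scale (3.40-fold, adjusted p = 0.00882). Hopx was 4.28-fold lower and Ccl5 is given above. Ifng fell by 2.75 ± 0.51 (6.74-fold, adjusted p = 0.0409), with an SD of 1.25 between the 2 IL15ko arrays (log2 differences of -1.87 without IL15ko 1 and -3.64 without IL15ko 2). Il12rb1 had a log2 difference of 0.35 ± 0.14 and an adjusted p of 0.183, and its other probe one of -0.32.

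Targets of STAT5, the transcription factor that IL-15 activates, were lower on balance. Of 16 measured members, 5 were called lower, 0 higher and 11 did not pass, and adjusted over the list alone 8 were lower and 1 higher. The mean was -0.82 (camera adjusted p = 0.000285, and adjusted p = 0.202 with an estimated correlation). Socs2 was 7.82-fold lower and Cish 6.13-fold lower, both feedback inhibitors of cytokine signalling, and Dusp6, a MAP kinase phosphatase gene, was 2.61-fold lower. The fold of Socs2 is uncertain, since it was well above background on 1 of the 2 IL15ko arrays only. Its log2 difference lay between -3.12 and -1.22 over 18 alternatives. Bcl2, the founding anti-apoptotic gene of its family, fell by 2.12 ± 0.25 on the log2 scale (4.34-fold, adjusted p = 0.0173). It was the only one of the 6 measured anti-apoptotic family members that was called. Bcl2l1 had a log2 difference of -0.80 ± 0.18 (adjusted p = 0.0589), and its other probe one of -1.998. Among the other members Bcl2a1c had one of -0.53 (adjusted p = 0.15), Mcl1 one of -0.26 (adjusted p = 0.298) and Bcl2l2 one of 0.82 (adjusted p = 0.115). Adjusted over the list alone, 2 were lower and 1 higher. The anti-apoptotic list as a whole was not called in the main setting (camera adjusted p = 0.0701), but was called lower in 8 of 21 alternatives. Of the 9 measured pro-apoptotic members 1 was called higher, Bak1 (1.76-fold, adjusted p = 0.0232), which was also the only one adjusted over the list alone. That list was not called either (camera adjusted p = 0.863), with camera pointing down and fry up.

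NKT17 genes, those of the IL-17-producing subset, were higher. Of 18 measured members, 12 were called higher, 0 lower and 6 did not pass, and 13 were higher when adjusted over the list alone. The mean log2 difference was 1.18 (camera adjusted p = 2.94e-09, and adjusted p = 0.202 with an estimated correlation). Il23r, a chain of the IL-23 receptor, rose 3.71-fold (adjusted p = 0.00786), Tmem176a rose 2.77-fold and Tmem176b 2.04-fold. Il17a was well above background on 1 IL15ko array only and Il17f on no array.

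NKT2 genes, those of the IL-4-producing subset, were also higher. Of 13 measured members, 10 were called higher, 1 lower and 2 did not pass, and 11 were higher and 1 lower when adjusted over the list alone. The mean was 0.93 (camera adjusted p = 5.2e-07, and adjusted p = 0.202 with an estimated correlation). Zbtb16, which encodes PLZF, the transcription factor of the NKT lineage, rose 2.83-fold (adjusted p = 0.0161), Irf4 rose 3.25-fold, the chemokine receptor gene Ccr7 3.17-fold, Slamf6 2.95-fold and Il13 2.33-fold. Il4ra fell by 1.59 on the log2 scale (3.02-fold, adjusted p = 0.0233). Il4 itself had a log2 difference of 0.66 ± 0.17 (adjusted p = 0.0867), and Gata3 one of 0.14 ± 0.20 (adjusted p = 0.682).

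Genes of NKT selection and lineage, and of naive and memory T cells, rose in part. Of 14 measured NKT lineage genes, 4 were called higher, 1 lower and 9 did not pass, against 7 higher and 1 lower when adjusted over the list alone. The mean was 0.62 (camera adjusted p = 0.000951, and adjusted p = 0.219 with an estimated correlation). Myb rose 3.22-fold, Slamf6 and Zbtb16 are given above, and Id2, an inhibitor of E proteins, fell by 0.80 on the log2 scale. Egr2 had a log2 difference of 0.39 and an adjusted p of 0.185. Of 13 measured naive and memory T-cell genes, 5 were called higher, 0 lower and 8 did not pass, against 8 higher and 2 lower when adjusted over the list alone. The mean was 0.56 (camera adjusted p = 0.00977, and adjusted p = 0.219 with an estimated correlation). Tcf7 rose 2.14-fold and Igfbp4 1.87-fold, whereas Klf2 had a log2 difference of -0.62 and an adjusted p of 0.0663.

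**Figure D2:**
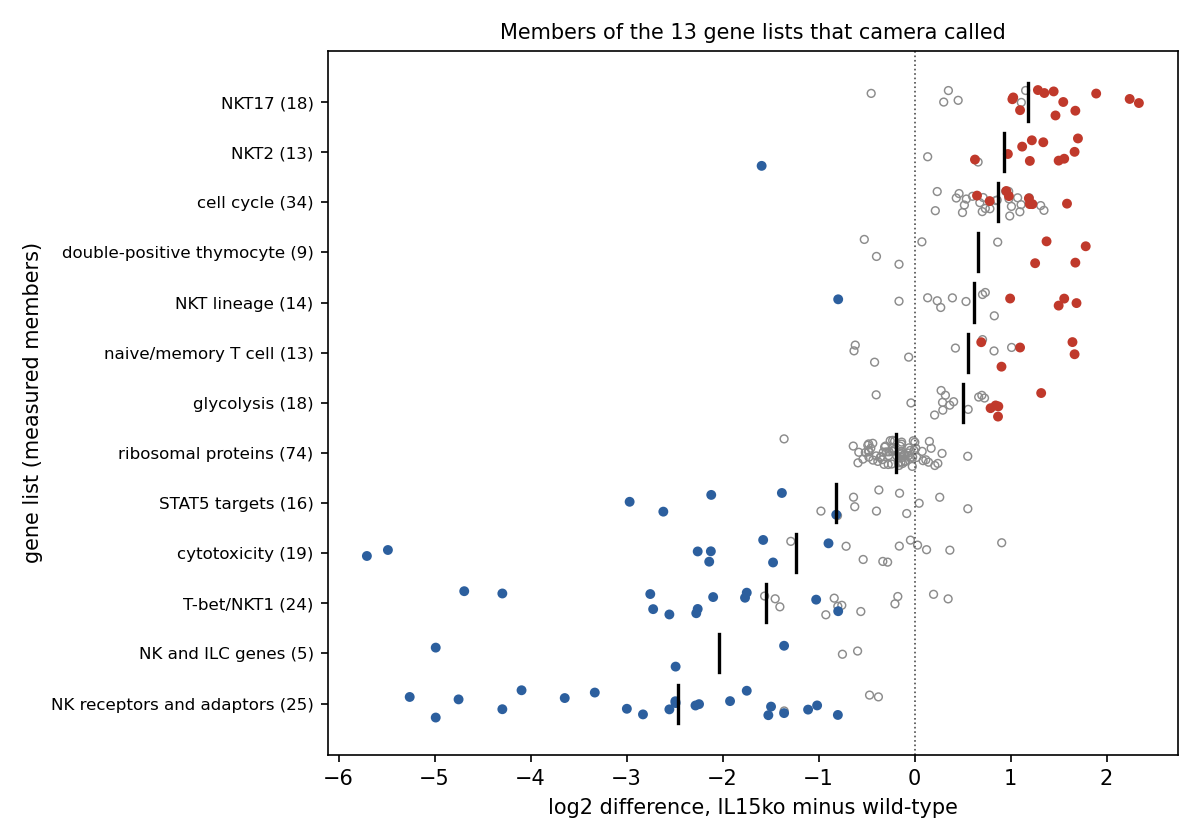
Log2 differences (IL15ko minus wild-type, horizontal axis) of the measured members of the 13 gene lists that camera called. Filled points are genes with an adjusted p under 0.05 over all genes (red higher, blue lower), open points are the others, and black bars are list means, from -2.46 for NK receptors to 1.18 for NKT17 genes. Vertical scatter within a list has no meaning.

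Cell-cycle genes were higher on balance. Of 34 measured members, 8 were called higher, 0 lower and 26 did not pass, and 17 were higher when adjusted over the list alone. The mean was 0.87 (camera adjusted p = 2.78e-10, and adjusted p = 0.356 with an estimated correlation). Wild-type 3 lay below both other wild-type arrays in 28 of the 34 members, and without it the mean was 0.68. Rrm2, a subunit of ribonucleotide reductase, rose 3.01-fold, the replication licensing gene Cdc6 2.34-fold, and the helicase genes Mcm5 and Mcm2 1.94-fold and 1.72-fold. Of 18 measured genes of glycolysis, 5 were called higher, 0 lower and 13 did not pass, against 10 higher when adjusted over the list alone. The mean was 0.51 (camera adjusted p = 1.38e-05, and adjusted p = 0.219 with an estimated correlation). Hk2, a hexokinase, rose 2.50-fold, Pkm 1.83-fold, Gapdh 1.83-fold (its 7 probes running from log2 differences of 0.09 to 1.16) and Pfkm 1.80-fold. The ribosomal protein list was called lower with a mean of -0.20 over 74 measured members (camera adjusted p = 0.000285, and adjusted p = 0.695 with an estimated correlation). None of its members was called, also when adjusted over the list alone, and the one with the smallest p, Rpl14, had a log2 difference of -0.58 and an adjusted p of 0.0718, and its other probe one of 0.48. This call was lost under quantile normalization (adjusted p = 0.103) and median centring (adjusted p = 0.0887).

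The list of double-positive and immature thymocyte genes was called higher, with 4 of 9 measured members called higher, 0 lower and 5 not passing, and 5 higher when adjusted over the list alone. The mean was 0.66 (camera adjusted p = 0.0302, and adjusted p = 0.219 with an estimated correlation), and without IL15ko 2 or wild-type 3 the adjusted p was 0.0984 and 0.145. The called members included Ccr9 (3.44-fold), Themis (2.59-fold) and Sox4 (2.39-fold), which other T cells also express, and Cd4 had a log2 difference of 0.87 and an adjusted p of 0.053. Rag1, Rag2, Ptcra, Cd8a and Cd8b1, abundant genes of that stage, were not well above background on any array.

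The remaining lists were not called by camera. Of 27 measured chemokine receptor and integrin genes, 7 were called higher and 7 lower, against 8 and 8 when adjusted over the list alone (mean -0.06, median 0.00, camera adjusted p = 0.863). Ccr9 and Ccr7 stood among the higher ones, and the integrin genes Itga1 (9.40-fold) and Itgb1 (2.88-fold) among the lower ones. Itga1 was not well above background on every array, so its fold is uncertain. Its log2 difference lay between -4.19 and -2.5 over 18 alternatives. Of 21 cytokine and chemokine genes, 4 were called higher and 5 lower, against 7 and 7 when adjusted over the list alone (adjusted p = 0.601), with Csf1 2.72-fold and Tnfsf11 2.21-fold higher. Of 29 interferon-induced genes, 1 was called lower, also when adjusted over the list alone (Gbp5, 1.87-fold), and camera gave an adjusted p of 0.176. Of 20 immediate-early and stress genes, 3 were called lower, Cd69 (3.22-fold), Klf6 (2.26-fold) and Dnajb1 (1.97-fold), and adjusted over the list alone 1 was higher and 3 lower (adjusted p = 0.56). Of 76 respiratory chain genes, 1 was called higher, Cox7a1 (2.05-fold), and 0 when adjusted over the list alone (adjusted p = 0.863).

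The remaining lists of markers of other cell types that a sort could hold were not called in the main setting. Some of their members were bright in both groups without a called difference, with log2 signals relative to the 75th percentile in wild-type and IL15ko of 5.32 and 5.13 for Siglech, 4.58 and 4.18 for Csf3r, and 3.13 and 2.57 for Hemgn, which were singled out after their values were seen. Other members of the same lists were dim, such as Mpo (-5.55 and -5.86) and Hba-a1 (-5.67 and -6.18), while Ermap (-1.19 and -1.25) lay between. Itgax, Flt3, Ltf, Mmp8, Alas2, Klf1 and Slc4a1 were not well above background on any array. The bright probes alone therefore do not show that such cells were present. Of 12 B-cell genes 3 were measured and 0 called, and adjusted over the list alone 1 was higher (Cd79b, log2 difference 0.92, camera adjusted p of the list 0.601). Of 15 macrophage genes 4 were measured and 0 called, against 1 higher and 1 lower when adjusted over the list alone (the latter Csf1r, log2 difference -2.28 with an adjusted p of 0.0509, -2.88 without IL15ko 1 and -1.69 without IL15ko 2, called in 6 of 19 alternatives, its 3 probes running from -2.28 to 0.28, camera adjusted p of the list 0.863). Of 14 dendritic-cell genes 9 were measured and 2 called higher, Ccr9 and Cd74 (2.09-fold), against 3 when adjusted over the list alone (mean 0.04, median -0.15, adjusted p = 0.601). Of 12 granulocyte genes 7 were measured and 1 called lower, S100a9, at least 3.26-fold lower in IL15ko (log2 difference of -0.712 and adjusted p = 0.402 with normexp and an offset of 50), also when adjusted over the list alone (adjusted p of the list 0.0717, called lower in 7 of 21 alternatives). Of 11 erythroid genes 4 were measured and 0 called (adjusted p = 0.84), with 0 adjusted over the list alone. Of 15 thymic epithelial and stromal genes 5 were measured and 0 called (adjusted p = 0.537), with 0 adjusted over the list alone. Of 10 regulatory T-cell genes 7 were measured, 2 called higher, Nrp1 and Ikzf4 (2.59-fold, its 3 probes running from log2 differences of -0.60 to 1.49), and 1 lower, Tnfrsf18 (2.02-fold), with the same counts when adjusted over the list alone (mean 0.32, median -0.08, adjusted p = 0.863).

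Genes that differ between the sexes also separated the groups. Xist, which is transcribed from the inactive X chromosome, was well above background on both IL15ko arrays and on 0 of the 3 wild-type arrays. The Y-linked genes Eif2s3y, Ddx3y and Uty fell by 1.98 ± 0.13, 1.36 ± 0.15 and 1.88 ± 0.17 on the log2 scale (adjusted p = 0.00591, 0.0164 and 0.0103), and Eif2s3y and Ddx3y remained well above background on both IL15ko arrays. Uty did not, and was at least 1.69-fold lower. These Y-linked genes were chosen after their values were seen. The labels do not give the sex of the mice. This difference ran alongside every gene group described here.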

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

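The test of genes near Il15 was chosen before its result was seen. The unnamed features were looked at only after the main comparison.

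Probes that carry no gene symbol lie outside the main comparison. When 8010 such features were tested together with the named genes, limma called 193 of them, 94 higher and 99 lower in IL15ko. The feature listed as NM_010400 was well above background on both IL15ko arrays and on 0 wild-type arrays, and was at least 20.3-fold higher in IL15ko (adjusted p = 0.0128). The feature listed as XIST was at least 168-fold higher (adjusted p = 0.0016). In the other direction, XM_001474162 had a log2 difference of -5.79 ± 0.13 (SE). None of these was given a gene name here.

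A strong probe signal in IL15ko alone may come from genes near Il15 carried from the strain in which the knockout was made. If many called genes had this source, tested genes next to Il15 would be called more often than others. Of the 200 tested genes nearest to Il15 on its chromosome, 13 were called, a share of 6.5% (exact binomial 95% interval 3.51 to 10.9), against 7.34% of all other tested genes (one-sided Fisher's exact p = 0.714). No excess was seen, but the interval includes shares above that of other genes, and the place of NM_010400 is not known here, so this explanation stays open for that probe. A difference of genotype and one of strain cannot be told apart for it with 2 groups of mice.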

How the results depend on the processing

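Alternatives named here as added were chosen after seeing the data. The 879 calls depend on the setting: 822 genes were higher and 698 lower with a trended, robust prior, 712 were higher with a filter for all 5 arrays, 142 higher (142 at least 2-fold) and 242 lower with a replicate block, 0 higher and 1 lower (at least 2-fold 0 and 1; 1958 at an unadjusted p under 0.05) with normexp at an offset of 50, and 0 higher and 3 lower (at least 2-fold 0 and 3; 2750) without a filter on dim probes. Added settings gave 33 higher and 63 lower (at least 2-fold 33 and 63) with wild-type 1 and 2 as 1 replicate, and 211 higher, 245 lower and 188 at least 2-fold higher among named genes when unnamed features were tested too. Leaving out 1 array gave 1 to 374 higher, 8 to 411 lower, 1 to 260 at least 2-fold higher and 8 to 330 at least 2-fold lower. More features tested and fewer samples are part of the construction of some of these, and otherwise the cause was not tested. The other alternatives stayed within 1.5 times of the main counts. All 879 genes kept their sign with each array left out, but this was fixed in advance, since the groups overlap in none of them. All 879 also kept it under quantile normalization and median centring, and 834 did with normexp at an offset of 50. The last raised the median log2 difference of all tested genes by 0.201 and median centring raised it by 0.146, and dropping the filter on dim probes raised it by 0.228. The replicate numbers are shared without any label that pairs them (deviations of same-numbered arrays correlate at -0.129 and 0.209), so the replicate block is no evidence of pairing. A slide or scan block was not run, since all arrays share 1 slide. Signal over background limits IL15ko 2 most, with 33.9% of probes well above it.

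Camera with an estimated correlation called 0 lists higher and 0 lower, and fry, which called 7 and 6, gave 0.121 for ribosomal proteins. None of the 13 called lists turned direction in any setting, and the calls of double-positive thymocyte and ribosomal protein genes were lost in some. Lists that the main setting did not call were called in some of 21 alternatives. These were anti-apoptotic genes in 8 (0.0426 without IL15ko 2), granulocyte genes in 7 (0.0192 without IL15ko 2), interferon-induced genes in 3, cytokine and chemokine genes in 1 (0.000909 with median centring), stress genes in 1 (0.000218 without IL15ko 2) and respiratory chain genes in 2 (0.00786 without IL15ko 2). Among lists that were not called, the mean log2 difference changed sign as follows, and the cause was not tested. With normexp at an offset of 50 it was 0.000222 for IL-15 signalling, 0.163 for pro-apoptotic, 0.111 for chemokine receptor, 0.0523 for granulocyte, 0.104 for erythroid, 0.407 for stromal and -0.0219 for respiratory chain genes (adjusted p = 0.0112). With median centring it was 0.0881 for IL-15 signalling and for chemokine receptor genes, 0.0249 for interferon-induced and 0.0495 for erythroid genes. Without the filter it was 0.167 for macrophage, -0.0473 for dendritic, 0.328 for erythroid and 0.0123 for stromal genes, and with the filter for all arrays 0.0858 for pro-apoptotic, 0.163 for chemokine receptor and 0.329 for stromal genes. Respiratory chain genes had -0.00355 in the authors' deposited table and -0.00319 with normexp without an offset, dendritic genes -0.168 with array weights and -0.242 with the replicate block, and erythroid genes 0.0292 with wild-type 1 and 2 as 1 replicate. Over left-out arrays the range was -0.348 to 0.133 for erythroid, -0.242 to 0.207 for dendritic, -0.123 to 0.00743 for IL-15 signalling, -0.72 to 0.39 for stress and -0.142 to 0.157 for respiratory chain genes, and for Gata3 it was -0.000165 to 0.277 and for Siglech -0.413 to 0.0192. Of 12 named genes given as a bound, 12 fell below it with normexp at an offset of 50, 9 in the authors' deposited table, 8 with normexp without an offset and at most 3 in any other setting. The offset adds the same amount to bright and dim signals, which shrinks such folds by construction. Of 84 named genes that were called, only Uty changed sign, to 0.0436 with normexp at an offset of 50.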

Other observations

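The tests of this part were chosen after the results were seen, except that of the share of X and Y genes. Genes of sterol synthesis and uptake, a group not among the lists, were chosen after their values were seen. Of 24 such genes, all measured, 4 were called lower in IL15ko and 0 higher. They included Sqle, which encodes squalene epoxidase (at least 4.37-fold lower, adjusted p = 0.00882, but a log2 difference of -1.44 and adjusted p = 0.067 in the authors' deposited table), and Stard4 (1.98-fold, adjusted p = 0.0372). Insig1 was also among them (4.28-fold, 95% confidence interval 2.07 to 8.85, adjusted p = 0.0476). It was well above background on 1 of the 2 IL15ko arrays only, so its fold is uncertain. Its log2 difference was -2.10 in the main fit, -1.45 without IL15ko 2 and -2.75 without IL15ko 1. Over 18 alternatives it lay between -2.75 and -0.101, and the call was lost in 11. Dhcr7 had a log2 difference of 1.22 ± 0.28 (SE) and an adjusted p of 0.0645. The mean over the 24 genes was -0.48 and the median -0.29, and camera gave p = 0.0217 at the preset correlation and p = 0.123 with an estimated one, so a lower level of the sterol-regulated genes as a set was not settled.

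NKT2 and NKT17 genes were higher and NKT1 genes lower in IL15ko. NK cells carried over into the wild-type pools could lower the killer-cell genes in IL15ko, but the T-cell enrichment and the CD3e gate would remove such cells. Of 8 NK and innate lymphoid genes outside the Klr receptors, 1 (Irf8) was well above background on all 3 wild-type arrays. Eomes was so on 1 wild-type array, and 5 of the 8 were so on none. This count cannot exclude some carry-over, since it rests on genes near the background. Fewer cells of 1 NKT1-like type that alone makes the genes of the NKT1 list, at unchanged levels per cell, would lower these genes by 1 common factor. The 11 called NKT1 genes measured on all 5 arrays fell by 0.80 (Id2) to 4.69 (Ccl5) on the log2 scale. The spread is beyond their errors (Cochran's Q = 190, p = 1.79e-35, n = 11 genes). This argues only against the form in which 1 cell type alone makes all these genes. Id2 is also on the NKT lineage list, so other NKT cells may make it. Fewer NKT1 cells, with some genes shared by other cells, were not tested by this. The errors come from 5 arrays, so the p of Cochran's Q is approximate, and differences in probe response were not tested. A lower share of NKT1 cells that raises NKT2 and NKT17 genes alike stays open, since the list means of 0.932 (13 genes) and 1.18 (18 genes) were not told apart (two-sided permutation p = 0.399 over 100000 resamples), as does an effect of IL-15 on gene expression within cells.

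Xist was higher and Y-linked genes were lower in IL15ko. Female cells in the IL15ko pools are a candidate explanation that stays open. That all 4 measured Y-linked genes were lower on both IL15ko arrays than on every wild-type array is the pattern itself, so it does not test this. Genes of the X and Y chromosomes as the source of the called genes are argued against, since 3.53% of the called genes lay there (28 on X, 3 on Y), against 3.22% of tested genes, and 436 genes higher and 412 lower were left without them. Sex-dependent expression of genes outside the X and Y chromosomes cannot be told apart from an effect of genotype, since 0 genotypes have arrays of both sexes known from the labels.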
